A study of Mus musculus with 2 samples.

How the data were processed

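Expression was measured by the authors in 2 biological replicates of 1 group, sorted mouse LT-HSC harvested after 48 h of culture. Per the labels' protocols, RNA was isolated on RNeasy micro columns, amplified with the Nugen Ovation system, labelled with biotin and hybridised to 1 array per sample. Amplification from small amounts of RNA adds technical spread, so the spread between the replicates holds both biological and technical parts.

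The deposited values were log2 signals per probe set made by the authors with RMA, per the submitters' processing notes, which name no version. RMA corrects background, normalizes arrays to each other and summarises the probes of a probe set. Which arrays were normalized together is not given in the sources used here, and the 2 samples do not share 1 distribution (SD of 1.85 in replicate 1 and 2.19 in replicate 2). Scanner files were not used here, and the values were used as deposited. RMA keeps no absolute scale and probes differ in affinity, so levels of different genes were not ordered against each other.

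The table held 45101 probe sets, of which 64 controls were left out of the tests. Gene names came from the platform annotation supplied with the values. Of the remaining 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in that table; genes were named only from the first kind. Of all probe sets with 1 gene, 34754 matched a gene of the GRCm38.p6 table by Entrez identifier, with 0 symbols changed, and 204 kept the older symbol. That table was used for names only, and no positions are given because the files name no genome build. In all 18193 genes had a probe set of their own. A gene counted as above background if any of its probe sets was, and its printed value is that of its probe set with the highest mean. The probe sets of 2193 genes disagreed on the call.

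With 1 group, the test the replicates allow is of a level against a fixed level. limma 3.58.1 in R 4.3.3 was fitted with an intercept to the log2 value minus the background level, with eBayes and a trend on the level, and a one-sided moderated p was adjusted by the Benjamini-Hochberg method over all 45037 probe sets at a threshold of 0.05. limma estimated infinite prior degrees of freedom, so that the spread used was the trend at each level (median SD 1.09) and a probe set's own spread did not enter. A gene therefore had to lie about 1.94 above the background level at the median spread, and a gene with very unequal replicates could pass. At an unadjusted p under 0.05, 7519 probe sets passed, against 5449 after adjustment. For all limma adjusted p-values n = 2 samples. They rest on that spread, pooled over probe sets, with total degrees of freedom of 45037. A very small p thus reflects distance from the background level and does not measure how well a gene's 2 replicates agree.

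The 26 gene lists, the background families, the main tests and the alternatives were chosen before the data were examined, except the settings, tests and lists that the text names as chosen later. The rule for named genes took every sort marker and supplied-factor receptor, the first 2 members of every other list (the first 3 of the sex-linked list), and the 10 genes above background with the largest difference in each direction between the replicates. A member without a probe set of its own was left out and not replaced. A further list member is not reported here. Any gene outside the rule is said to have been chosen after its values were seen. The neutrophil and interferon genes labelled in the scatter plot are of this kind, as are all genes of the lists added for the closing section. A gene list's median difference between the replicates (replicate 2 minus replicate 1) was set against 10000 random lists matched on mean level in 20 bins. A planned comparison of each list's median level with random lists is left out, since it would set probe sets of different affinity against each other. These percentiles describe the 2 samples and carry no p-value. A loess of the difference on the mean (span 0.3) was removed as an alternative. Random lists and tables were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Alternatives covered the background percentile and gene set, the trend, the probe set rule, centring, leaving out each replicate, and the filters and scaling behind the differences between replicates.

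The test was tested on simulated data for 45037 probe sets. With errors drawn at the spread typical of each level and the levels as measured, limma called 14.8% of probe sets lying about 1 above the background level, 95.4% at 3 and 100% at 4, and 0.289% of its calls lay under the level. Where 50 probe sets were placed at each of 4 margins over an array otherwise at background, 2%, 4%, 52% and 98% were called at margins of 1, 2, 3 and 4. A first noise model, in which the spread differed strongly between probe sets, gave lower recovery, and the model above was adopted after that result was seen. With that first kind of noise the calls were 0.903%, 21.4%, 59.6% and 74.7% with levels as measured, and 0% of the placed probe sets at every margin. A gene not above background may thus still be expressed. For the shifts, lists of 12 random genes moved by 0, 0.5, 1 and 2 lay over the central 95% of matched lists in 2, 22, 75 and 100 of 100 draws.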

Results

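Gene expression was measured with an Affymetrix mouse array in long-term haematopoietic stem cells (LT-HSC), the rare bone marrow cells able to rebuild the blood system, after 2 days in culture. The cells came from C57BL/6 mice. They had been sorted as negative for lineage markers, among them CD127 (Il7r), and for CD34 and CD135 (Flt3) and positive for Sca-1 and CD117 (Kit), to a purity given as over 98%. They were then kept for 48 h in StemSpan medium containing stem cell factor at 10 ng/ml, thrombopoietin at 20 ng/ml, FGF-1 at 10 ng/ml, and IGFBP2 and Angptl5 at 100 ng/ml each. The series title names Flt3 ligand where the culture protocol names FGF-1, and the data do not settle which was used. The series holds 1 group of 2 samples that the labels call biological replicates, and cells before culture were not analysed here. The values therefore give levels after culture and the spread between the replicates, not a change over culture. The log2 signal had a median of 5.60 in replicate 1 and 5.51 in replicate 2 over 45037 probe sets, with an SD of 1.85 and 2.19. The number of arrays limits the precision of every value.

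The first question was which genes the cultured cells expressed. Most measured genes of the cell cycle, glycolysis, oxidative phosphorylation and cholesterol synthesis, and 12 of 19 haematopoietic transcription factors, lay above the array background level. Mecom, a transcription factor needed to maintain stem cells, stood at 11.34 ± 0.12 (log2 signal, mean ± SD, n = 2, as for all levels given with an error). Gata2, a transcription factor of stem and progenitor cells, stood at 10.60 ± 1.23, and Pcna, the sliding clamp of DNA replication, at 11.85 ± 0.33. Gata1, the main erythroid transcription factor, stood at 5.42 ± 0.08 and Cd79a, a part of the B cell receptor, at 5.21 ± 0.03, both under the background level of 6.36. In all, 3490 of 18193 genes (19.2%) were above background by limma's one-sided moderated test, with Benjamini-Hochberg adjustment. The background level was the 95th percentile of the mean signal of 150 probe sets for olfactory, vomeronasal and taste receptors, keratin-associated proteins and beta-defensins. limma judged each probe set against the spread typical of its level and not by its own 2 values, and 13 of the 5449 probe sets above background had 1 sample at or under that level. The count was 9618 genes for replicate 2 alone and 6076 for replicate 1 alone, each against its own background level with no test. It was 1131 where both samples were tested against their own background levels, a setting chosen after seeing the data.

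Among 18 measured genes associated with LT-HSC, 7 were above background (8 when adjusted over the list alone). Hlf, a transcription factor of stem cells, stood at 8.93 ± 1.89 (limma adjusted p = 0.00107) and Mecom 4.98 above the background level (limma adjusted p = 1.91e-36). Mecom passed through 1 of its 3 probe sets, and not by their mean. Of 19 haematopoietic transcription factors, 12 were above background (14 when adjusted over the list alone). Gata2 passed with a limma adjusted p of 7.21e-18, while Runx1, needed for stem cells to form in the embryo, stood at 7.97 ± 0.47 and did not pass (limma adjusted p = 0.149). Myb and Lmo2, singled out after their values were seen, read 12.24 and 11.90 in replicate 1 and 12.37 and 11.93 in replicate 2. Without a test, 17 LT-HSC genes and 19 transcription factors exceeded background in replicate 2 alone, against 9 and 15 in replicate 1 alone. With the mean of a gene's probe sets, 4 LT-HSC genes passed. LT-HSC genes numbered 3 and transcription factors 7 with the 99th percentile as background level, and 2 and 7 with each sample's own background level.

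Genes of the surface markers used for sorting and of the receptors for the supplied factors gave mostly low values. Kit, the stem cell factor receptor and a positive sort marker, stood at 7.92 ± 1.82 and did not pass the test (limma adjusted p = 0.170), although it passes when adjusted over the list alone, where it is the 1 measured gene. Its level was 6.64 in replicate 1 and 9.21 in replicate 2. Cd34, whose protein the sort selected against, was above background at 9.41 ± 1.23 (limma adjusted p = 9.41e-06), in both replicates (8.54 and 10.28), but not with each sample's own background level, where 0 of the 3 negative sort markers passed and 1 did at an unadjusted p under 0.05 by limma. Flt3 stood at 6.35 ± 1.08 and Il7r at 4.20 ± 0.06, and neither passed, although Flt3 exceeded background in replicate 2 alone, without a test. Of the 3 measured negative sort markers 1 was above background, also when adjusted over the list alone. Of 9 measured genes listed as receptors for supplied factors, limma placed 0 above background, 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05. The 9 count Kit and Flt3, and also Igf1r and Igf2r, although the culture protocol names no IGF. Igf1r stood at 8.05 ± 0.25, Fgfr1 at 6.04 ± 0.19, Fgfr2 at 5.96 ± 0.21, Fgfr3 at 6.67 ± 0.09, Fgfr4 at 4.78 ± 0.68, Pirb, an Angptl receptor, at 6.01 ± 0.81, and Igf2r at 6.61 ± 1.23. Without a test, 4 receptors exceeded background in replicate 2 alone, 2 in replicate 1 alone and 3 in both samples against the common level. By limma 1 receptor passed with the 90th percentile as background level and 2, Igf1r and Kit, with a background list of tissue-restricted genes. Sca-1 (Ly6a) had no probe set of its own in the annotation used here and was not analysed.

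Among genes listed for the supplied factors themselves, Kitl, which encodes stem cell factor, was above background at 8.59 ± 2.85 (limma adjusted p = 0.0109), as 1 of 4 measured genes (1 when adjusted over the list alone). The 4 include Igf1, although the culture protocol names no IGF. Kitl read 10.61 in replicate 1 and 6.57 in replicate 2. The call rested on 1 of its 4 probe sets, and the mean of its probe sets lay 0.50 under the background level (-0.50).

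Most cell cycle genes were above background in both phases tested. Of 21 S phase genes 15 passed (16 when adjusted over the list alone), with Pcna 5.49 above the background level (limma adjusted p = 2.26e-59) and Mcm2, a subunit of the replicative helicase, at 8.09 ± 1.98 without passing (limma adjusted p = 0.0982). Of 19 G2 and M phase genes 13 passed (15 when adjusted over the list alone). Mki67, a marker of cycling cells, stood at 9.81 ± 0.68 and Cdk1, the mitotic kinase, at 10.25 ± 0.75. Of 10 inhibitors of cyclin-dependent kinases and quiescence genes 3 were above background (3 when adjusted over the list alone). These were Cdkn1b (p27) at 8.88 ± 0.37, Foxo3 at 10.54 ± 0.65 and Rb1, the last 2 named after their values were seen. Cdkn1a (p21) stood at 7.39 ± 0.86 and did not pass. Of these 10 genes, 9 exceeded background in replicate 2 alone and 6 in replicate 1 alone, without a test.

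Targets of cytokine signalling through JAK and STAT were above background in 6 of 11 cases (7 when adjusted over the list alone). Socs2 stood at 10.95 ± 0.45, through 1 of its 6 probe sets, and Cish at 8.99 ± 0.21, both feedback inhibitors of this pathway. Socs1 and Socs3, 2 further feedback inhibitors, stood under the background level at 4.15 ± 1.06 and 6.12 ± 0.40. Among the 6 that passed were the D cyclins Ccnd1, Ccnd2 and Ccnd3, which are also cell cycle genes. These 5 genes were named after their values were seen. With the mean of a gene's probe sets, 3 of the 11 passed. Of 10 immediate early genes, which respond within minutes to growth factors and stress, 1 passed (1 when adjusted over the list alone). It was Egr1 at 9.21 ± 0.75, named after its value was seen, while Fos stood at 4.30 ± 0.43 and Jun at 6.06 ± 0.68. Immediate early genes over background numbered 5 in replicate 2 alone and 1 in replicate 1 alone.

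Most metabolic genes passed. Of 9 glycolysis genes 8 were above background (9 when adjusted over the list alone), with lactate dehydrogenase Ldha at 11.04 ± 0.79 and hexokinase Hk2 at 9.33 ± 0.66. Of 13 oxidative phosphorylation genes 12 passed (13 when adjusted over the list alone), with the complex II subunit Sdhb at 9.67 ± 0.16 and the complex I subunit Ndufs1, which did not pass, at 7.71 ± 1.61. Of 12 cholesterol synthesis genes 11 passed (11 when adjusted over the list alone), the exception being Mvd, named after its values were seen. Of the cholesterol genes, 7 passed with the mean of a gene's probe sets and 5 with each sample's own background level.

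Stress response genes were above background in part. Of 12 genes of the unfolded protein response 4 passed (7 when adjusted over the list alone, and 7 with the 90th percentile or with tissue-restricted genes as background), with the chaperone Hspa5 at 10.38 ± 0.47 and Ddit3 (CHOP) at 8.16 ± 0.37 without passing. Of 10 p53 targets 3 passed (3 when adjusted over the list alone), with Mdm2 at 9.28 ± 0.88. With the mean of a gene's probe sets limma placed 0 p53 targets above background, and 1 at an unadjusted p under 0.05, while 1 passed with each sample's own background level. Of 9 interferon response genes 1 passed (1 when adjusted over the list alone). It was Bst2 at 8.99 ± 1.28, named after its values were seen, while Ifit1 stood at 6.15 ± 0.40 and Irf7 at 6.94 ± 0.19. With replicate 2 alone and with replicate 1 alone, the counts were 9 and 7 for the unfolded protein response, 7 and 6 for p53 targets and 8 and 2 for the interferon response.

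Other lists also lost calls under stricter background levels. With the 99th percentile and with each sample's own background level, the counts were 8 and 7 for G2 and M phase, 1 and 1 for inhibitors and quiescence, 4 and 4 for the cytokine response, 3 and 2 for the unfolded protein response and 2 and 0 for neutrophil genes. Immediate early, interferon response and sex-linked genes and those for the supplied factors each went from 1 to 0 under both, and monocyte genes from 1 to 0 under the latter. At an unadjusted p under 0.05 by limma, neutrophil genes then numbered 2, those for the supplied factors 0 and the other lists of these 1 each.

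**Figure D1:**
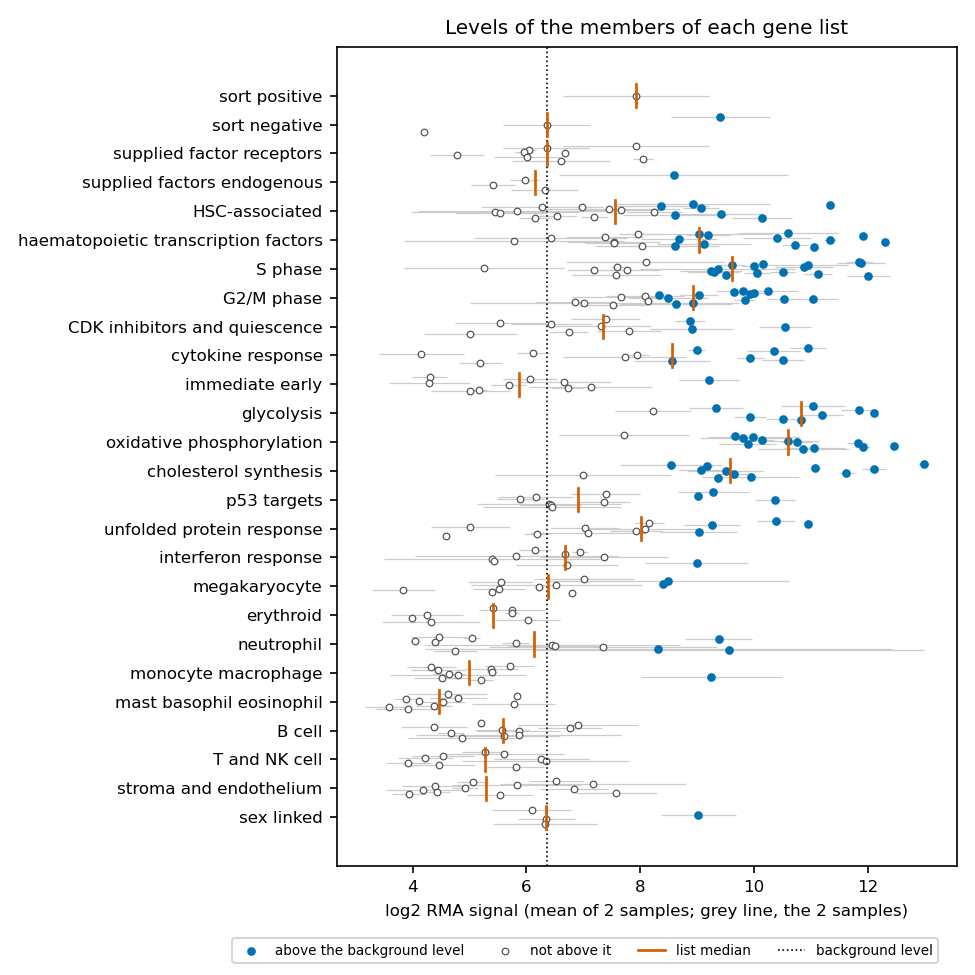
Levels of the measured members of the 26 gene lists: the horizontal axis is log2 RMA signal, each point is 1 gene's mean of the 2 samples, and the grey line through it joins the 2 samples. Filled points are above the background level (dotted line, 6.36) by limma's test, and orange bars are list medians. All points of the glycolysis, oxidative phosphorylation and cholesterol synthesis lists lie to the right of the dotted line, and all points of the mast cell list to its left.

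Markers of other blood cells and of stroma, which the sort should remove or the culture could produce, were mostly at background. limma placed 0 of 7 erythroid, 0 of 10 mast cell, basophil and eosinophil, 0 of 10 B cell, 0 of 9 T and NK cell and 0 of 12 stromal and endothelial genes above it. These counts were also 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. With replicate 2 alone and with replicate 1 alone, B cell genes numbered 2 and 1, T and NK cell genes 2 and 1 and stromal genes 3 and 3. Klf1, Mcpt8, Cpa3, Cd3e, Cd8a, Col1a1 and Cdh5 had means between 4.61 (Cpa3) and 6.52 (Col1a1). Of 10 megakaryocyte genes 2 passed (2 when adjusted over the list alone). These were the platelet chemokine Pf4 at 8.49 ± 3.001 (limma adjusted p = 0.0181) and Gp9, named after its values were seen, at 8.40 ± 0.07, while Itga2b (CD41) stood at 7.01 ± 1.24. Both calls ended with the 99th percentile and with each sample's own background level, where limma placed 0 megakaryocyte genes above background and 0 at an unadjusted p under 0.05. Of 12 neutrophil genes 3 passed (3 when adjusted over the list alone): Prtn3, named after its values were seen, at 9.38 ± 0.84, and S100a8 and S100a9, whose replicates differed widely. Mpo and Elane, enzymes of granulocyte precursors, stood at 4.46 ± 0.70 and 5.04 ± 0.22. Of 10 monocyte and macrophage genes 1 passed (1 when adjusted over the list alone), Lyz2 at 9.25 ± 1.75, named after its values were seen, whose probes may also detect its paralog Lyz1. Csf1r and Itgam stood at 5.70 ± 0.61 and 4.33 ± 0.61. Megakaryocyte and neutrophil genes over background numbered 6 and 1 in replicate 2 alone and 1 and 6 in replicate 1 alone. The Y-linked Eif2s3y was above background at 9.02 ± 0.94, as 1 of 4 sex-linked genes (1 when adjusted over the list alone; 2 with replicate 2 alone), and Xist stood at 6.09 ± 0.98 without passing.

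The second question was how far the replicates agreed. Among genes above background, each read on its probe set of highest mean, the widest gap lay in S100a8 and S100a9, which encode the calprotectin of neutrophils. S100a8 read 12.43 in replicate 1 and 4.21 in replicate 2, and S100a9 read 12.99 and 6.13, so that in replicate 2 both lay under the background level of 6.36. In the other direction the gap was widest for Pttg1 (securin, a regulator of chromosome separation) at 6.07 in replicate 1 and 10.80 in replicate 2. Pf4 read 6.37 and 10.62. No test compares 1 sample with 1 sample, so these are differences between these 2 samples.

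The other 8 genes with the largest log2 differences towards replicate 1 (replicate 2 minus replicate 1) were Maged2 (-5.22), Tirap (-5.12), Tcim (-5.08), Cavin2 (-4.64), Peli1 (-4.52), Ceacam1 (-4.40), Tubb2a (-4.09) and Wsb2 (-4.04). Further probe sets differed the other way, by 0.08 for Maged2, 2.12 for Tirap, 1.62 for Wsb2 and, in 3 cases, at least 0.09 for Peli1, where the widest read 3.76 in replicate 1 and 6.76 in replicate 2. Towards replicate 2 they were the histidyl-tRNA synthetase Hars (4.52), Sephs1 (4.41), Hacd3 (4.24), Dnajc15 (4.05), the complex I subunit Ndufs3 (3.78), Ifi35 (3.71), Ddost (3.68) and the pyruvate dehydrogenase kinase Pdk1 (3.63). Further probe sets of Sephs1 and Ifi35 differed the other way (-0.07 and -0.40), and one of Hacd3, of lower mean, read 6.57 in replicate 1 and 11.56 in replicate 2, a wider gap than that of Pttg1. Maged2, Tcim and Cavin2 in replicate 2 and Pttg1 and Sephs1 in replicate 1 lay under the background level of 6.36, so the size and order of these differences rest in part on values at background. Among genes above background, 1405 differed by over 1, 1099 of them (78.2%) higher in replicate 2 and 306 higher in replicate 1. After a loess of the difference on the mean was removed, the split was 519 to 564 (47.9% higher in replicate 2). Where a second probe set of the gene was also above background, it differed in the same direction for 188 of 212 genes higher in replicate 2 (88.7%, against 71.97% of all 892 genes with a second probe set) and for 32 of 63 genes higher in replicate 1 (50.8%, against 28.03%).

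Over all probe sets Pearson's r between the replicates was 0.777 and Spearman's rho 0.718. These are correlations across probe sets, which are not independent replicates. The difference had a median of -0.13 and an SD of 1.39, and 53.2% of probe sets agreed within 1 log2 unit. Background probe sets such as olfactory receptors were higher in replicate 1 in 127 of 150 cases, with a median difference of -0.71, or -0.32 after the loess step. Probe sets with a mean between 7 and 8 had a median difference of 0.89, and those between 11 and 15 one of 0.15.

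**Figure D2:**
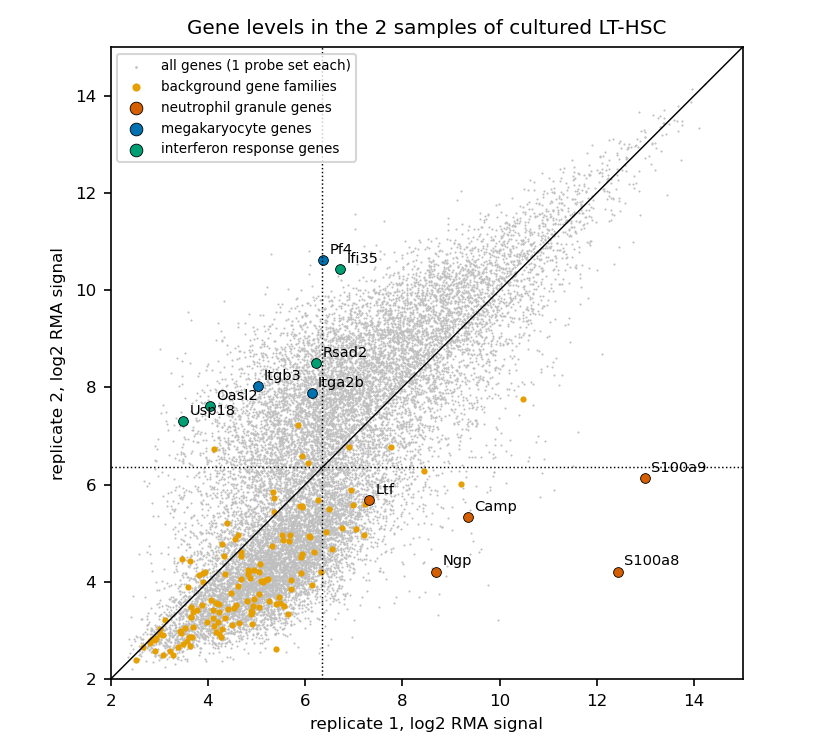
Log2 RMA signal of 18193 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 probe set per gene, with the line of equality and the background level of 6.36 (dotted). Small light orange points are background gene families. Large points, labelled after their values were seen, are neutrophil (dark orange, called granule genes in the plot), megakaryocyte (blue) and interferon response (green) genes. S100a8 and S100a9 lie far to the right at 12.43 and 12.99 in replicate 1, against 4.21 and 6.13 in replicate 2.

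Haematopoietic transcription factors were higher in replicate 2 by a median of 1.35, above 99.9% of 10000 random lists matched on mean level, with 18 of 19 members higher there. Interferon response genes were higher in replicate 2 by a median of 1.80, above 99.04% of matched lists, with 6 of 9 members higher there. Rsad2, Oasl2 and Usp18, named after their values were seen, read 6.23, 4.04 and 3.49 in replicate 1 and 8.50, 7.61 and 7.30 in replicate 2. After the loess step the medians were 0.60 (above 97.9% of matched lists) and 1.20 (above 97.8%). Among members above background alone, the transcription factors' median was 0.62, above 81.2% of matched lists, and with the mean of a gene's probe sets it was 0.97, above 89.4%. Bst2, the 1 interferon response gene above background, differed by 1.81, above 85.5% of matched genes. These were the 2 of 26 lists outside the central 95% of matched lists, where 1.3 lists would lie outside by chance. The neutrophil list had a median of -0.88, above 6.85% of matched lists, while its mean was -2.24, under all of them (0%). Stem cell genes had a median of 1.19, above 97.4% (1.48, above 99.85%, with the mean of a gene's probe sets), and p53 targets one of -0.42, above 5.44% (0.21 with the mean of a gene's probe sets). S phase, G2 and M phase, glycolysis and oxidative phosphorylation genes had medians of 0.47, 0.96, 0.64 and 0.55, each inside that range. The sign of the median turned after the loess step for the cytokine response (0.45 to -0.32), cholesterol synthesis (0.02 to -0.16) and sex-linked (0.16 to -0.31) lists, and after quantile normalization for the megakaryocyte list too (0.12 to -0.04). With the mean of a gene's probe sets it turned for the unfolded protein response (0.59 to -0.02) and for cholesterol synthesis (-0.16, above 0.78% of matched lists).

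**Figure D3:**
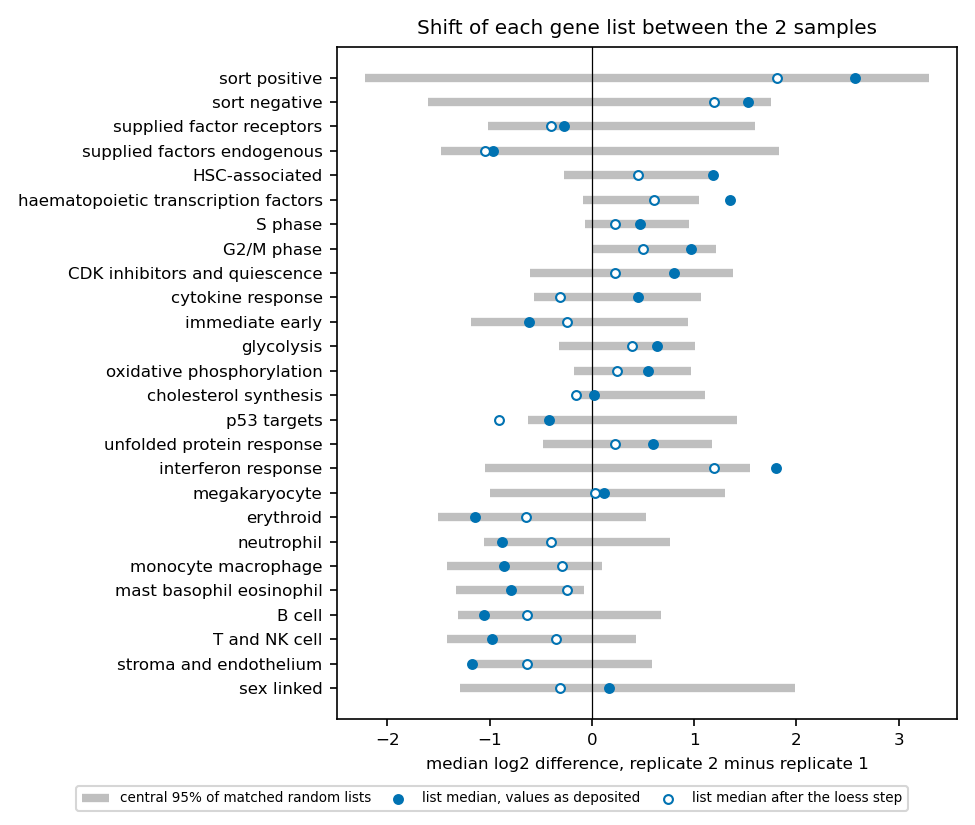
Median log2 difference, replicate 2 minus replicate 1, of each of the 26 gene lists, as deposited (filled) and after the loess step (open). Grey bars hold the central 95% of random lists matched on mean level and apply to the values as deposited, not to the open points. The filled points of the haematopoietic transcription factors (1.35) and the interferon response (1.80) lie to the right of their bars.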

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

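The tests of 3' bias and of an unequal distribution were chosen after the result was seen, and the test of probe sets without a gene symbol before it.

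Control probe sets for mouse ribosomal RNA and short interspersed repeats, which the comparisons do not use, gave signal over the background level of 6.36. The middle, 5' and 3' probe sets for 18S ribosomal RNA read 12.38, 9.43 and 6.96 in replicate 1 and 11.92, 7.86 and 6.94 in replicate 2. The B1 repeat probe set read 12.77 and 11.73, and 2 probe sets for B2 repeats read 11.85 and 9.39, and 14.29 and 13.73. The 3 repeat probe sets read higher in replicate 1, while the 3' set for 18S was nearly equal. Such repeats occur in introns and untranslated regions. The 4 probe sets for pyruvate carboxylase, also mouse controls, had means of 4.67 to 6.04, under the background level.

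Replicate 1 also had a narrower range of values, with background families higher by a median of 0.71 (-0.71 as replicate 2 minus replicate 1) and most expressed genes lower. RNA broken or copied from the 3' end would raise the 3' minus 5' difference of the control transcripts in replicate 1, but its median excess there was -0.12 (actin -0.12, Gapdh 0.36, transferrin receptor -2.86, the last with a 5' probe set near the floor). A distribution left unequal by the authors' normalization is argued against as the whole cause, since giving both samples 1 distribution left the background families at -0.41 (95% bootstrap interval -0.54 to -0.27). Bootstrap intervals here and below are over probe sets or genes within these 2 arrays, and do not measure the spread between samples. Unspliced or repeat-derived sequence in replicate 1, a candidate explanation that the B1 and B2 values bring up, stays open: 9160 probe sets without a gene symbol stood lower in replicate 2 than named ones by only -0.11 after the loess step. Hybridisation and scanning stay open as untested, with the bacterial spike-in controls also spanning less in replicate 1 (the middle bioB probe set read 12.04 against 11.13 in replicate 2, and the 3' cre probe set 14.67 against 14.64), and since the design has 1 group no biological explanation was tested.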

How the results depend on the processing

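Settings using each sample's own background level, both samples above background beside the limma test, quantile normalization or a list without its most different member were chosen after the data were seen. No paired analysis was possible because the series has 1 group. The count of 3490 genes above background became 1808 with the 99th percentile, 6687 with both samples above and no test, 2181 with the mean of a gene's probe sets (1965 of them among the 3490), 1131 with each sample's own background level, and 6076 to 9618 with 1 replicate left out and no test. It stayed between 3285 and 4420 under the other 6 settings. With the mean of a gene's probe sets the members above background fell from 13 to 8 for G2 and M phase, 15 to 10 for S phase, 3 to 2 for cell cycle inhibitors and 1 to 0 for both the supplied factors and the sex-linked genes (0 of each at an unadjusted p under 0.05 by limma). The 105 list members became 56 with each sample's own level and 135 to 177 with 1 replicate left out. Kitl (-0.50) and Tcim (-0.055) fell under the background level by the mean of their probe sets. With 1 replicate left out the level above background ran from -0.60 to 4.45 for Pf4, -1.95 to 5.45 for S100a8, -0.034 to 6.02 for S100a9, -0.42 to 3.85 for Tcim, -0.27 to 4.14 for Maged2, -0.25 to 4.27 for Ifi35 (these 2 kept the call through another probe set), -0.90 to 4.63 for Pttg1, -0.88 to 4.35 for Sephs1, -0.20 to 4.67 for Dnajc15 and -0.30 to 4.14 for Pdk1, by construction, since their replicates differ. Of the other values of named genes, over all settings, 718 kept their side of the threshold, 83 lost the call and 39 gained it. Pearson's r of 0.777 was 0.624 over probe sets above background and 0.579 over the others, a narrower range of levels, and Spearman's rho was 0.718. The 1405 differing genes became 9157 with no filter on low values, 2654 with a mean at least 1 above background, 733 at a difference over 1.5 and 859 with the mean of a gene's probe sets. The share higher in replicate 2 was 78.2%, 50.7% with no filter, 47.9% after the loess step and 52.0% after quantile normalization. The 2 lists outside the central 95% became 5 with the mean of members (supplied factors, neutrophil and stromal genes joined), 5 with the mean of a gene's probe sets (LT-HSC, negative sort, cholesterol and neutrophil genes joined, transcription factors left) and 3 over members above background (supplied factors, neutrophil and monocyte genes); the cause was not tested. For the neutrophil list the median itself stayed at -0.88 with the mean of a gene's probe sets, and only its matched lists changed. Signal over background limits low genes: the test needed a margin of about 1.94.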

Other observations

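The second lists of neutrophil and interferon genes and the predictions for them were written before their values were seen, but after those of the first lists were. The tests of all-marrow cells and of 5 neutrophil genes, and the bootstrap interval asked of the interferon list, were chosen after the results were seen. So were all gene groups of the next paragraph.

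Gene groups outside the fixed lists ranged from all to none of their measured members above background. All 17 measured proteasome subunits passed limma's test, among them Psma7 at 11.15 ± 0.30 and Psmb1 at 10.81 ± 0.40 (n = 2). Of 18 chromatin regulators 10 passed, with the maintenance DNA methyltransferase Dnmt1 at 12.05 ± 0.44 and the de novo enzyme Dnmt3b at 10.18 ± 0.53, while Ezh2 (8.14 ± 1.67) and Tet2 (6.62 ± 1.37) did not. Of 15 adhesion and homing genes 8 passed, with the Cxcl12 receptor Cxcr4 at 9.98 ± 0.05, the hyaluronan receptor Cd44 at 9.61 ± 0.10 and the laminin receptor subunit Itga6 at 10.01 ± 0.50. Of 17 DNA repair genes 6 passed, with Parp1 at 11.07 ± 0.37, Brca1 at 9.33 ± 0.32 and Chek1 at 9.60 ± 0.85, all 3 higher in replicate 1. The DNA repair list as a whole was higher in replicate 2 for 14 of 17 members, with a median of 1.14 (above 93.1% of matched lists, inside their central 95%). After the loess step it was 0.82 (above 97.9%, just outside their central 95%). As it was 1 of several lists chosen after results were seen, each read on both scales, chance is not excluded. Several of these calls rested on 1 probe set of several, as for Parp1, Brca1 and Cd44 (1 of 4 each) and Psmb1 (1 of 3). Of 15 imprinted genes 2 passed, Grb10 at 11.38 ± 0.13 through 1 of 3 probe sets and Gnas at 10.66 ± 0.92 through 1 of 5. Dlk1 read 4.40 in replicate 1 and 8.86 in replicate 2 without passing. Of 20 Hox genes other than Hoxa9 and Hoxb5, limma placed 0 above background and 1 at an unadjusted p under 0.05, while Hoxa9 stood at 8.68 ± 0.95 and passed. A second list of 25 genes, put together as megakaryocyte and platelet genes, had 9 above background. Among them were the thrombin receptor F2r at 10.18 ± 1.13 and Fermt3 at 10.18 ± 0.54, while F2rl2 stood at 5.14 ± 0.15 and did not pass. Members such as Cd9, which also stands in the adhesion list, are not particular to megakaryocytes, so the count does not show a megakaryocyte programme. Vwf (7.66 ± 0.99), Selp (8.14 ± 0.98), Gp6 (4.22 ± 0.56) and Thbs1 (4.87 ± 0.35) were among those that did not pass.

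Among neutrophil genes, 5 picked for their difference were higher in replicate 1. They included the granule genes Camp, Ngp and Ltf, at 9.35, 8.70 and 7.32 there against 5.33, 4.21 and 5.67 in replicate 2. The others were S100a8 and S100a9, whose calprotectin lies mainly in the cytosol, at 12.43 and 12.99 against 4.21 and 6.13. Prtn3 read 8.78 and 9.97, and Ctsg (-0.18) and Elane (-0.31) differed little. A second list of 23 neutrophil genes, 4 of them above background, had a median of -0.92 after the loess step (interval -1.61 to -0.27). This was under all but 0.44% of matched lists, whereas the list fixed in advance had a median of -0.40, above 26.9%. In the values as deposited, 12 members of the second list were over 1 higher in replicate 1 against 2 the other way. Lcn2 read 8.72 in replicate 1 and 3.31 in replicate 2, Chil3 7.52 and 3.49, Mcemp1 8.77 and 5.15 and Clec4d 10.34 and 7.82. Of these, only Clec4d was above background. The other members above background did not share the direction: Pglyrp1 read 8.63 and 8.62, Anxa1 9.64 and 10.22 and Lyz1 8.64 and 10.63. The percentile of the second list goes against the narrower range of replicate 1 as the whole cause, but does not settle it. After the loess step the background families still stood at -0.32, inside that list's interval. Of its 23 members, 13 were at or under the background level in both samples. The 5 genes themselves, though picked for their difference, lay at -2.07 to -8.94 after the loess step (median -4.89). A few neutrophils or their RNA in replicate 1, despite the lineage-negative gate, are a candidate explanation and no more. Mmp8 (5.17) and Hp (4.84) were under the background level in replicate 1, and the fixed list did not stand apart by its median. Before the loess step that list did stand apart by its mean (-2.24, under all matched lists). With the mean of a gene's probe sets it lay above 1.4% of matched lists, but its own median stayed at -0.88. Each of its measured members has 1 probe set, so only the matched lists changed. Over members above background the median was -6.86, the difference of S100a9, with S100a8 and Prtn3 as the other members. S100a8 and S100a9 passed that filter only through replicate 1, so neither value is further support. Marrow cells of other kinds stay open too. By the median after the loess step 0 of 7 other cell type lists stood apart towards replicate 1, but by that measure the fixed neutrophil list did not either. By the mean of members before that step, the stromal list stood apart as well (-0.997, above 0.93% of matched lists). Expression of these genes by the cultured cells themselves is also open and untested.

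Interferon response genes were higher in replicate 2, with a list median of 1.20 after the loess step (95% bootstrap interval -0.54 to 3.60, above 97.8% of matched lists). The median and its percentile met the bound written beforehand under which the narrower range of replicate 1 would not be the cause. The interval over 9 genes, chosen after the result was seen, is wide and takes in negative values, so that cause is left open. A second list of 23 interferon genes, which includes the already named Ifi35, was higher in replicate 2 by a median of 0.61 (interval 0.04 to 1.19), above 93.1% of matched lists and inside their central 95%, short of the bound set beforehand. Whether replicate 2 had an interferon response cannot be told apart from chance differences between 2 samples, and with 1 group no biological explanation was tested further.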
